A study of Homo sapiens with 6 samples.

How the data were processed

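Total RNA of 143B cells was sequenced in 6 samples, 3 infected with lentiviral shRNA against JAB1 and 3 scrambled controls. The treatment protocol is worded the same for all 6 samples, and the groups were taken from the treatment field of each sample. The conditions of the deposited table were matched to these groups by the sample titles. The titles carry the codes D1, D2 and E1 for the knockdown and N1A, N1B and N2A for the scrambled samples. Whether samples with a shared letter or number came from the same shRNA or culture is not given in the sources used here, and if they did, the p-values are too small. Per the labels' protocols, cells at passage 12 were infected at a multiplicity of 5 and selected in puromycin at 0.5 µg/mL, with 72 h given for the selection step, ribosomal RNA was removed, stranded libraries were made with the TruSeq Stranded Total RNA kit, and 50 M single-end reads of 50 bp were planned per sample. The submitters' processing notes name Trim Galore, STAR, Cufflinks and Cuffdiff and the build GRCh38. No versions of these tools and no annotation release are given in the sources used here, nor is the strand setting of the counting. The labels' extraction protocol also names CLC Genomics Workbench.

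The authors deposited a Cuffdiff table with 1 line per gene and library, in 2 conditions of 3 libraries numbered 0 to 2. Those numbers match no sample title, so each library was used as an unnamed member of its group, and it could not be said which of the 2 shRNAs a knockdown library had. Per the file headers, the table holds estimated counts of fragments per gene before scaling and FPKM values, which are scaled by gene length and depth, made by the authors with Cuffdiff. Some of the estimated counts that the authors deposited were fractional, and all were rounded before testing. A status column was used as a filter, and 3 further per-library columns were not used. The authors also deposited their own Cuffdiff comparison, with a log2 fold change, a p-value and a q-value for each gene. Its log2 fold changes are scrambled over knockdown per the file headers, and their sign was turned here. Of 58024 genes, 74 lay in loci that Cuffdiff skipped for too many fragments in 1 or both groups, and these were left out. Another 36 with a failed estimate were kept.

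Totals ranged from 19.5 to 31.6 M fragments per library over all genes, with loci that were skipped in the other group alone included. Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, the quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05, with group as the single factor. The filter left 15929 genes. Adjusted p-values below are edgeR's unless another tool is named, log2 fold changes are knockdown over scrambled, CPM values were scaled with TMM factors, and errors on CPM are SDs over the 3 libraries of a group. The test on counts, the 24 gene lists, the genes to be named and the first set of other settings were fixed before the data were examined. Lists were tested with limma 3.58.1's camera at a preset correlation of 0.01, adjusted over the 23 lists with at least 3 tested members. The epithelial marker list had 2 of 10 members tested and was left out. For each list, the uncorrected counts of genes are also given adjusted over the list alone, and the corrected counts printed are so too where the values differ.

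Genes were named by a fixed rule. COPS5, CDKN1A and MDM2 were named whatever their result. The rule added the 10 genes with the largest change in each direction past the threshold, with a mean log2 CPM of at least 1, a symbol naming 1 gene that is not a clone-based, LOC, antisense or pseudogene name, and all knockdown libraries on 1 side of all scrambled libraries. From each list, up to 4 members with the smallest adjusted p could be named, or 2 where none passed. Some genes that met the rule are not reported here, and genes named outside it are said to be so.

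GC content and length were taken from the longest transcript of each gene in GENCODE release 29, using protein-coding transcripts where a gene had any. Of the 58024 genes, 99.0% matched it by identifier, and 99.5% of those tested had a GC value. After a relation between fold change and GC content had been seen, a corrected fit was added, in which a natural spline with 5 degrees of freedom of GC content and another of log10 length were fitted in each library and used as offsets in edgeR. Fold changes from it are called corrected below. Because the relation separates the groups, the correction also removes any real change that follows GC content or length.

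Other settings fixed in advance were other scaling factors, other filters, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, stricter thresholds, the authors' q-values, camera with an estimated correlation or on ranks, fry, and each library left out in turn. Settings added after the data had been seen were the corrected fit, a fit corrected for GC content alone, protein-coding genes only, genes with a failed estimate left out, and the library of each group furthest along GC content left out, with and without the correction.

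The steps were tested on simulated data made from the means and library sizes of the knockdown against scrambled comparison. Among 15788 simulated genes, edgeR called 47 of 50 genes changed 4-fold, 32 of 100 changed 2-fold and 6 of 15558 unchanged genes. For genes changed 1.5-fold, edgeR called 0 of 50 and DESeq2 8 of 50. When the GC and length relation of the real libraries was added, edgeR called 4759 of 15589 unchanged genes, and 1 with the correction. The added relation came from the same splines that the correction fits and removes. Its removal was thus fixed in advance and does not show how well the correction works on the real libraries. On the same simulated data the corrected fit called 45 of 50 genes changed 4-fold, 17 of 100 changed 2-fold and 0 of 50 changed 1.5-fold, against 46, 61 and 23 without correction, and DESeq2 was not run on them. The share of changed genes was far smaller in the simulation than the 54.2% called in the real libraries, or 33.2% with the correction. Its dispersions also came from the fit without correction. The simulated rates thus do not give the sensitivity of the real tests. A simulated list of 30 raised genes had a camera p of 5.1e-15, and a list of 30 unchanged genes had 0.137. Simulated genes were drawn independently of each other, while estimated correlations in the real lists reached 0.331 (G2/M and mitosis) and 0.538 (histones). These single lists thus do not show how camera with the preset correlation does on the real lists. Unlike camera, limma's fry also passed the unchanged list at 0.05, with a fry p of 0.0107 against 0.000116 for the raised list.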

Results

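The series asked how JAB1 acts in osteosarcoma and whether this depends on p53. JAB1, encoded by COPS5, is the catalytic subunit of the COP9 signalosome, which removes the ubiquitin-like protein NEDD8 from cullins. RNA was measured in 143B cells, a metastatic human osteosarcoma line derived from HOS cells, after lentiviral knockdown with shRNA against JAB1 (3 libraries) or with a scrambled control (3 libraries). Knockdown libraries 0, 1 and 2 held 21.7, 19.5 and 19.5 M fragments, and scrambled libraries 0, 1 and 2 held 31.6, 30.2 and 25.3 M. The labels call the samples independent without saying how, so p-values measure the spread between these samples. Pearson's r of log2 CPM across genes was 0.993 between scrambled libraries 1 and 2, and 0.979 between each of them and library 0. Between knockdown libraries 1 and 2 it was 0.983, against 0.967 and 0.957 with library 0. Whether these closer pairs shared an shRNA or culture cannot be told, and if they did, the p-values are too small.

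The targeted gene was lower in every knockdown library. COPS5 (ENSG00000121022.13, chromosome 8, 67043079 to 67083783 of GRCh38, minus strand) had 19.2, 25.1 and 24.9 CPM in knockdown libraries 0, 1 and 2, from 386, 467 and 482 fragments. The scrambled libraries had 73.8, 57.3 and 56.8 CPM, from 2379, 1805 and 1490 fragments. The means were 23.1 ± 3.34 and 62.6 ± 9.69 CPM (SD, n = 3), so 36.9% of the transcript level remained by the fitted fold change. COPS5 fell, with a log2 fold change of -1.44 (SE 0.18, adjusted p = 0.00084) and a corrected change of -1.62 (SE 0.13, adjusted p = 0.000202). An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest that 3 against 3 libraries allow.

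**Figure D1:**
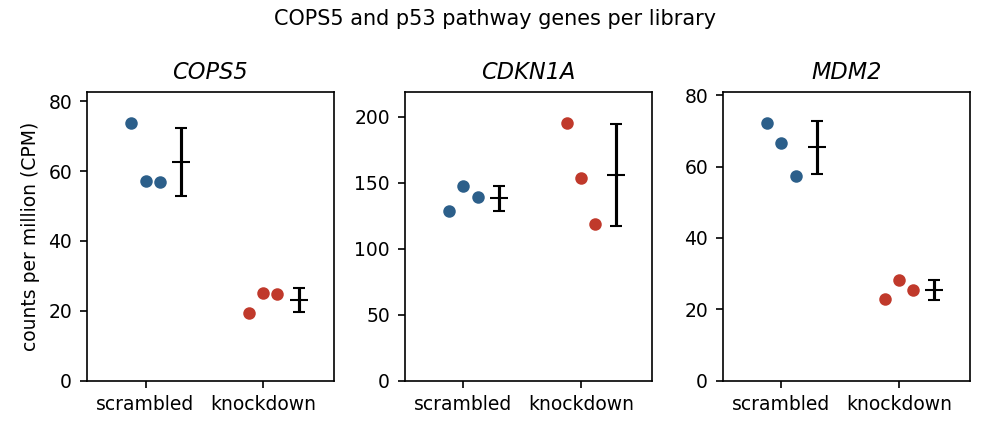
CPM of COPS5, CDKN1A and MDM2 in each scrambled (blue) and knockdown (red) library, with the mean and SD of each group (n = 3) in black on axes that start at 0. COPS5 and MDM2 were lower in all 3 knockdown libraries, at means of 23.1 and 25.5 CPM against 62.6 and 65.4, while the groups overlap for CDKN1A.

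The knockdown and scrambled libraries differed across much of the transcriptome. Of 15929 genes tested, 4347 rose and 4283 fell in the knockdown libraries, together 54.2%, and 2826 and 2215 of these changed at least 2-fold. Genes rich in GC were higher and genes poor in GC were lower: across genes, which are not independent replicates, Spearman's rho between fold change and GC content was 0.779, and with length it was -0.339. Among 2113 genes with over 60% GC, the median log2 fold change was 1.41 and 1511 rose. Among 2263 genes with under 40% GC, the median was -0.99, 1581 fell and 17 rose. In the corrected fit 2626 genes rose and 2662 fell, 3361 of the 8630 calls held in the same direction and 151 turned to the opposite one. Corrected values are therefore given beside the fold changes below.

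**Figure D2:**
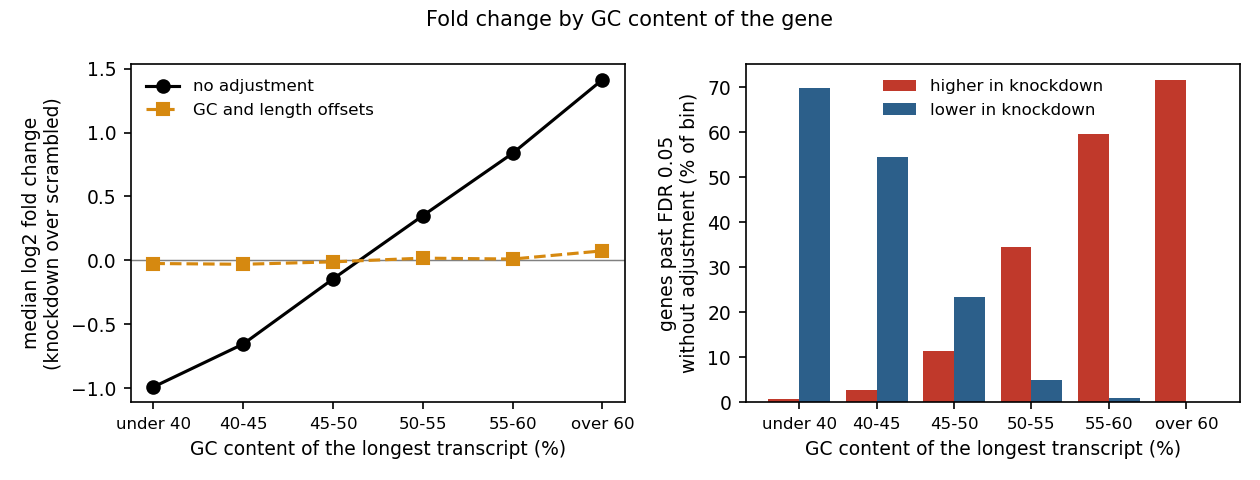
Median log2 fold change, knockdown over scrambled, by GC content of the longest transcript in % (left), without correction (black circles) and with GC and length offsets (orange squares), and the share of genes in each bin past an FDR of 0.05 without correction (right; red higher, blue lower in knockdown). The median goes from -0.99 under 40% GC to 1.41 over 60%, and with the offsets it lies between -0.03 and 0.07.

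The genes with the largest falls had mixed functions. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, fell from 279 ± 6.28 to 37.7 ± 5.76 CPM (SD, n = 3), a log2 fold change of -2.89 (SE 0.15, corrected -1.84). ENPP1, an ectoenzyme that makes pyrophosphate and limits mineralisation, fell by a log2 of -2.92 (SE 0.18, corrected -2.06), from 222 to 29.3 CPM. Among the others were ARRDC3 (-2.88, corrected -1.88), the adhesion protein gene FLRT3 (-2.66, corrected -1.68), the interferon-induced IFI44 (-2.56, corrected -1.80), the inhibitor of apoptosis BIRC3 (-2.55, corrected -1.43), the cytokine gene IL1A (-2.52, corrected -1.78), the inositol transporter gene SLC5A3 (-2.50, corrected -1.41) and the ion channel gene TRPA1 (-2.47, corrected -1.53). Adjusted p-values of these 9 genes ranged from 0.000469 to 0.00149, and all 9 also fell in the corrected fit.

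Among the 10 genes with the largest rises, IL24, SPNS2 and MYPN depended least on knockdown library 0, with log2 fold changes of 4.90, 5.30 and 4.54 without it. IL24 and MYPN moved more with other libraries: without knockdown library 2 they stood at 4.01 and 3.76, and MYPN at 5.37 without scrambled library 1. IL24, a cytokine of the IL-10 family, rose from 1.48 ± 0.27 to 37.9 ± 23.5 CPM (SD, n = 3), a log2 fold change of 4.68 (SE 0.47, adjusted p = 0.000537, corrected 4.63). SPNS2, the sphingosine-1-phosphate exporter, rose by 6.13 (SE 0.69, adjusted p = 0.000663, corrected 4.60), from 0.18 to 12.9 CPM. MYPN, a sarcomere protein gene, rose by 4.41 (SE 0.70, adjusted p = 0.00193, corrected 4.66). For the other genes knockdown library 0 carried much of the rise: without it the log2 fold change went from 5.85 to 2.47 for SCAND1, from 4.83 to 2.91 for the respiratory complex I gene NDUFB7, from 4.45 to 2.89 for DGCR6L, from 4.33 to 2.74 for RPUSD1, from 4.25 to 1.94 for the interferon-induced ISG15, from 4.11 to 2.01 for HIST1H4I and from 4.45 to 3.07 for HIST1H2AH. Their corrected values with all libraries were 4.04, 2.64, 2.63, 2.33, 2.31, 4.24 and 2.60. Several rises started near the floor, so their size is poorly determined. Scrambled means were 0.21 CPM for SCAND1, 0.40 for DGCR6L, 0.39 for ISG15, 0.18 for SPNS2 and 0.18 for MYPN. The authors' deposited table gave SCAND1 a q of 0.0806. The call for ISG15 ended in the corrected fit (adjusted p = 0.0531) and without scrambled library 0 (0.0536), that for HIST1H4I without scrambled library 0 (0.0521), and that for SCAND1 without scrambled library 0 or 1 (up to 0.0688).

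**Figure D3:**
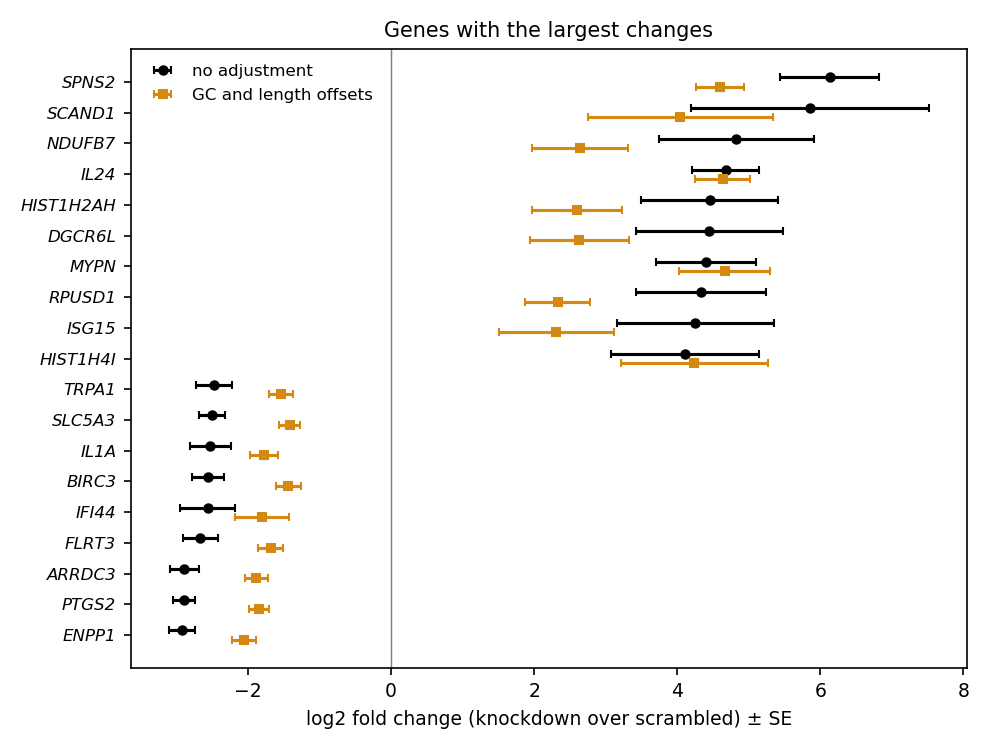
Log2 fold change, knockdown over scrambled, with its SE for the 10 genes with the largest rise and for 9 of the 10 with the largest fall, without correction (black circles) and with GC and length offsets (orange squares). Every point keeps its side of 0 with the offsets, and IL24 (4.68 and 4.63) and MYPN (4.41 and 4.66) move least among the genes that rose, with HIST1H4I (4.11 and 4.24).

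Target genes of p53 moved in both directions. MDM2, a ubiquitin ligase gene (chromosome 12, 68808176 to 68850686), fell from 65.4 ± 7.54 to 25.5 ± 2.75 CPM (SD, n = 3), a log2 fold change of -1.36 (SE 0.16, adjusted p = 0.000695, corrected -0.51, adjusted p = 0.015). CDKN1A, the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339), had 156 ± 38.4 and 138 ± 9.48 CPM and did not pass (0.17, SE 0.19, adjusted p = 0.459), yet fell in the corrected fit (-0.78, SE 0.12, adjusted p = 0.00206). Of 32 p53 target genes, 9 rose, 10 fell and 13 did not pass, with the same counts adjusted over the list alone. SERTAD1 (1.93, corrected 1.40) and the nuclease gene AEN (1.11, corrected 0.45) rose, and the helicase gene ASCC3 (-1.77, corrected -0.77) fell. The list's median was 0.05, its mean -0.05 and its camera direction down (adjusted p = 0.716), and with library size alone as scaling the median was -0.05. With the correction, 8 rose and 11 fell (median -0.08, camera adjusted p = 0.519).

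Other subunits of the signalosome and the enzymes around cullins changed in part. Of the 9 other COP9 subunits, 4 rose, 1 fell and 4 did not pass, and 2 of the 4 also rose in the corrected fit. COPS2, chosen after its values were seen, fell without correction (-0.74, adjusted p = 0.037) and turned to a rise in the corrected fit (0.39, adjusted p = 0.0486). COPS7A rose by 0.98 (SE 0.12, corrected 0.42) and GPS1, which encodes subunit 1, by 1.95 (SE 0.37, corrected 0.40). COPS6 (0.74, corrected 0.15) and COPS9 (0.63, corrected -0.46) rose only without correction, and these calls ended without knockdown library 1 (COPS6, adjusted p = 0.0611) and without any of 4 single libraries (COPS9, up to 0.0807). Of 31 genes of neddylation and cullin-RING ligases, 7 rose, 14 fell and 10 did not pass, against 8 and 5 in the corrected fit. The cullin exchange factor CAND1 fell by a log2 of -1.77 (corrected -0.75) and the cullin CUL4B by -1.43 (corrected -0.40), and KEAP1, a substrate adaptor of cullin 3, rose by 1.63 (corrected 0.57). The NEDD8-conjugating enzyme UBE2M rose by 0.90, which the correction ended (-0.64, adjusted p = 0.105). Counts adjusted over the list alone were the same for both lists. Neither list passed camera (adjusted p = 0.359 and 0.215, corrected 0.487 and 0.626), but the neddylation list passed in the downward direction with no filter beyond 1 count (0.00495). With the main filter and its estimated correlation of 0.238, camera gave the neddylation list an adjusted p of 0.734. In the corrected fit its camera direction was up.

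More mitotic genes fell than rose, and more histone genes rose than fell, but the list calls ended with an estimated correlation. Of 28 genes of G2/M and mitosis, 18 fell, 3 rose and 7 did not pass (median -0.86, camera adjusted p = 0.000124, and adjusted p = 0.606 with an estimated correlation). With the correction, 18 fell (median -0.45, camera adjusted p = 1.59e-05, and adjusted p = 0.675 with an estimated correlation), 15 of them in both. CENPF, a kinetochore protein gene, fell by a log2 of -2.01 (SE 0.15, corrected -1.06), the spindle motor KIF11 by -1.74 (corrected -0.73), the topoisomerase TOP2A by -1.78 (corrected -0.77) and the checkpoint kinase TTK by -1.65 (corrected -0.85). Of 16 replication-dependent histone genes tested, 15 rose (median 1.68, camera adjusted p = 4.95e-09, and adjusted p = 0.606 with an estimated correlation), and 9 in the corrected fit (median 0.86, camera adjusted p = 1.31e-05, and adjusted p = 0.675 with an estimated correlation). HIST1H2BG rose by 1.58 (corrected 1.45), HIST1H4B by 2.62 (corrected 1.79) and HIST1H2AG by 1.68 (corrected 1.80), while the rise of HIST1H3J by 1.69 ended with the correction (0.17, adjusted p = 0.47). Histone genes are near-identical copies, so values of single members are uncertain. Of 24 genes of homologous recombination and the DNA damage checkpoint, 16 fell, 3 rose and 5 did not pass (median -0.90, camera adjusted p = 0.000512, and adjusted p = 0.606 with an estimated correlation), among them FANCI (-1.27, corrected -0.64), NBN (-1.68, corrected -0.63) and RAD50 (-1.68, corrected -0.79), but the list's call ended in the corrected fit, where 6 fell and 2 rose (median -0.24, adjusted p = 0.152). With correction for GC content alone it still passed (median -0.29, adjusted p = 0.026). XRCC3 rose by 1.53, which the correction ended (0.26, adjusted p = 0.273). Another gene covers 79.7% of the exon length of RAD50 on the same strand and 76.7% of that of XRCC3 on the opposite strand, so both are uncertain. Of 29 genes of G1/S and DNA replication, 9 rose, 13 fell and 7 did not pass, or 11 and 15 adjusted over the list alone, with a median of -0.45, a mean of 0.00 and a camera direction down (adjusted p = 0.647). In the corrected fit 2 of them rose and 9 fell, or 3 and 11 adjusted over the list alone (median -0.18, camera adjusted p = 0.282). The helicase subunit MCM6 (-1.29, corrected -0.71) and the ribonucleotide reductase RRM1 (-1.31, corrected -0.75) fell. The transcription factor E2F1 rose by 1.48 and the DNA polymerase subunit POLA1 fell by a log2 of -0.99, and the correction ended both calls (0.20, adjusted p = 0.338, and -0.29, adjusted p = 0.0514). Without correction, counts adjusted over the list alone were the same for the other lists, and with it 1 mitotic gene rose that did not over all genes.

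Histone and short non-coding RNAs also took larger shares of the knockdown libraries. Histone genes held 2.0%, 1.94% and 1.29% of fragments in knockdown libraries 0, 1 and 2 and 0.51%, 0.60% and 0.60% in the scrambled libraries. Short non-coding RNA genes held 1.62%, 1.13% and 0.65% against 0.16%, 0.23% and 0.24%. Of 66 such genes tested, 40 rose, with a median of 1.56, and 25 rose and 2 fell in the corrected fit (median 0.63). Much of the short non-coding share in the knockdown libraries lay in RPPH1 and RMRP, chosen after their values were seen. Their more abundant entries had means of 5367 and 4900 CPM, against 466 and 849 in the scrambled libraries. Corrected changes were 1.42 (adjusted p = 0.00526) and 0.68 (adjusted p = 0.0579). Signal recognition particle RNA genes in loci skipped in the knockdown libraries had no value there and are left out of the shares.

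More genes of cholesterol synthesis fell than rose. Of 20 genes, 9 fell, 2 rose and 9 did not pass, also adjusted over the list alone (median -0.30, camera adjusted p = 0.0232, and adjusted p = 0.606 with an estimated correlation). With the correction, 11 fell, or 14 adjusted over the list alone (median -0.42, camera adjusted p = 1.31e-05, and adjusted p = 0.133 with an estimated correlation), 9 of them in both. HMGCS1, which makes HMG-CoA, fell from 225 to 57.3 CPM, a log2 fold change of -1.98 (SE 0.17, corrected -1.15). The sterol transport gene STARD4 changed by -1.81 (corrected -0.70) and the sterol sensor INSIG1 by -1.24 (corrected -0.99). The list's call without correction also ended on ranks (0.151), with limma-voom (0.183), with protein-coding genes only (0.065) and with a filter of at least 50 counts in 3 libraries (0.0705).

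Stress response genes divided. Of 26 genes of the integrated stress and unfolded protein response, 13 rose, 8 fell and 5 did not pass (13 and 9 adjusted over the list alone, camera adjusted p = 0.302), against 5 and 7 in the corrected fit. PPP1R15A, the phosphatase subunit that reverses eIF2α phosphorylation, rose by 2.27 (SE 0.15, corrected 1.31) and the amino acid transporter subunit SLC3A2 by 2.01 (corrected 1.15), while EDEM1 (-1.60, corrected -1.12) and SEL1L (-1.60, corrected -0.56), both of endoplasmic reticulum-associated degradation, fell. Of 18 NRF2 targets, 7 rose, 4 fell and 7 did not pass (camera adjusted p = 0.327), against 5 and 1 in the corrected fit. Heme oxygenase HMOX1 rose by 2.44 (SE 0.21, corrected 1.46) and the ferritin light chain FTL by 1.95 (corrected 1.01), the latter with near-identical copies. The malic enzyme ME1 fell by a log2 of -1.20 (corrected -0.33) and the cystine transporter SLC7A11 by -1.36, which the correction ended (-0.19, adjusted p = 0.296). Of 26 hypoxia genes, 5 rose, 8 fell and 13 did not pass (camera adjusted p = 0.359), and P4HA1 (-1.53, corrected -0.81) and LDHA (-1.16, corrected -0.76) fell. The correction ended the fall of BNIP3L (-0.93, corrected -0.01) and the rise of the enolase ENO1 (0.78, corrected -0.21). The hypoxia list passed in the corrected fit, where 1 rose and 8 fell (median -0.26, adjusted p = 0.0103, and 0.675 with an estimated correlation). Adjusted over the list alone, the NRF2 and hypoxia counts were the same.

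Several interferon, cytokine and adhesion genes fell. Of 22 interferon response genes, 8 fell, 4 rose and 10 did not pass. IFIT2 (-2.41, corrected -1.77), IFIT3 (-2.03, corrected -1.65) and the RNA sensor DDX58 (-1.97, corrected -1.10) fell. Of 20 NF-kB and cytokine genes, 6 fell, 4 rose and 10 did not pass, with PTGS2, BIRC3 and IL1A among those that fell, while the cytokine gene IL11 rose by 1.99 (SE 0.18, corrected 1.31). Of 27 invasion and mesenchymal genes tested, 9 fell, 4 rose and 14 did not pass, and 2 of the 30 listed lay in loci that Cuffdiff skipped. The integrin subunits ITGB1 (-1.87, corrected -0.998) and ITGAV (-1.86, corrected -0.76) and the osteoblast cadherin CDH11 (-1.79, corrected -1.05) fell, and S100A4 rose by 2.18 (corrected 1.46). Without correction, counts adjusted over the list alone were the same, and each of these 3 lists had a camera adjusted p of 0.215. In the corrected fit all 3 passed in the downward direction, at 0.0191 for the interferon list (9 fell and 2 rose, or 10 and 3 adjusted over the list alone), 0.0103 for the NF-kB list (8 fell and 1 rose, or 9 and 3) and 0.0191 for the invasion list (10 fell and 3 rose, the same), but with an estimated correlation at 0.51, 0.693 and 0.693. Uncorrected, all 3 also passed with no filter beyond 1 count (interferon 0.0486, NF-kB 0.033, invasion 0.0314), the NF-kB list without knockdown library 2 (0.0499), and the invasion list without knockdown library 0 (0.045) and without both this and scrambled library 0 (0.00149). These calls rest on the preset correlation. Uncorrected camera with an estimated correlation, the main filter and all libraries gave adjusted p-values of 0.606 (interferon), 0.689 (NF-kB) and 0.734 (invasion).

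BMP, TGF-beta, AP-1 and osteoblast genes showed no common direction. Of 20 genes of BMP and TGF-beta response, 8 rose, 4 fell and 8 did not pass (9 and 4 adjusted over the list alone, camera adjusted p = 0.302). The inhibitors ID3 (1.87, corrected 0.88) and SMAD7 (1.36, corrected 0.53) rose, and the receptors TGFBR1 (-1.50, corrected -0.47) and TGFBR2 (-0.97, corrected -0.74) fell. Of 11 AP-1 subunits, 3 rose, 1 fell and 7 did not pass (camera adjusted p = 0.481), against 2 and 4 in the corrected fit. ATF3 rose by 1.22 (corrected 0.96), and ATF2 fell by a log2 of -1.02, which the correction ended (0.01, adjusted p = 0.972). JDP2 rose by 0.84 (corrected 0.75), and BATF3 rose by 0.70 and turned to a fall with the correction (-0.81, adjusted p = 0.0428). Without scrambled library 2 the calls for BATF3 (adjusted p = 0.0516) and JDP2 (0.0624) ended. Of 15 osteoblast lineage genes, 3 rose, 2 fell and 10 did not pass (camera adjusted p = 0.773). The decoy receptor TNFRSF11B (osteoprotegerin) fell by a log2 of -1.75 (corrected -1.19), and the homeobox gene MSX2 rose by 0.87 (corrected 0.90). ATF4 (1.08, corrected 0.27) and BMP7 (0.73, corrected 0.10) rose only without correction. Adjusted over the list alone, the AP-1 and uncorrected osteoblast counts were the same.

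Lists of growth and survival genes held changes both ways. Of 25 MYC response genes, 13 rose, 6 fell and 6 did not pass (14 and 7 adjusted over the list alone, camera adjusted p = 0.215), against 6 and 4 in the corrected fit (8 and 5 adjusted over the list alone). The ribosome assembly gene RRP9 rose by 2.24 (corrected 0.98) and nucleolin, NCL, fell by a log2 of -1.03 (corrected -0.82). NOP2, which shares 54.4% of its exon length with another gene, rose by 1.30 (corrected 0.68), and NOP16 rose by 0.93, which the correction ended (0.29, adjusted p = 0.0599). Of 31 proteasome subunits, 13 rose, 10 fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.466), against 7 and 6 in the corrected fit (8 and 6 adjusted over the list alone), and PSMD8 rose by 1.37 (corrected 0.69). The rises of PSMC4 (0.98, corrected 0.27) and PSMC3 (0.98, corrected 0.17) and the fall of PSMD12 (-1.19, corrected -0.19) ended with the correction. Of 29 apoptosis regulators, 10 rose, 9 fell and 10 did not pass (11 and 10 adjusted over the list alone, camera adjusted p = 0.762). MCL1, which protects cells from apoptosis, fell from 990 ± 5.59 to 342 ± 22.4 CPM (SD, n = 3), a log2 fold change of -1.53 (SE 0.11, corrected -1.13). The caspase activator APAF1 fell by a log2 of -1.65 (corrected -0.79), and the pore-forming BAK1 rose by 1.76 (corrected 0.73). The apoptosis list had a median of 0.05, a mean of 0.02 and a camera direction down. Of 13 mitochondrially encoded mRNAs, MT-ND6, MT-ND3, MT-ND4L and MT-CO3 fell (adjusted p = 0.0217 to 0.0363), which held neither adjusted over the list alone nor in the corrected fit. Each of these 4 calls also ended without at least 1 library (adjusted p up to 0.114), and the list did not pass (median -0.49, camera adjusted p = 0.294, corrected -0.45 and 0.433). The list passed in the downward direction with no filter beyond 1 count (median -0.57, adjusted p = 0.0486) and without scrambled library 0 (median -0.82, adjusted p = 0.00966). Without both knockdown library 0 and scrambled library 0, chosen after the data had been seen, its median was -0.99 (adjusted p = 8.19e-05), or -1.11 in the corrected fit (adjusted p = 3.49e-10). These small values rest on the preset correlation of 0.01: with all libraries the estimated correlation of the list was 0.816 (corrected 0.911), and camera with it gave an adjusted p = 0.786 (corrected 0.825).

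Markers of other cell types were sparse. Of 13 blood markers, 3 could be tested, and CD68 (38.1 to 107 CPM, adjusted p = 0.019) and CD14 (1.74, adjusted p = 0.0197) rose, also adjusted over the list alone, with neither passing in the corrected fit (adjusted p = 0.0912 and 0.222). CD14 stood at 0.60 CPM in the knockdown libraries, and its call ended without knockdown library 0 or scrambled library 0 or 2 (adjusted p up to 0.0771), while 81.7% of the exon length of CD68 lies in another gene on the same strand. Of 10 endothelial markers, 5 could be tested: TIE1 rose by 1.03, ERG fell by a log2 of -0.75 and 3 did not pass, also adjusted over the list alone. In the corrected fit TIE1 stood at 0.02 and ERG at -0.43 (adjusted p = 0.95 and 0.0988), and the calls ended without scrambled library 0 (TIE1, 0.0546) and without knockdown library 1 or scrambled library 1 or 2 (ERG, up to 0.0662). The camera adjusted p was 0.302 for the blood list and 0.97 for the endothelial list, whose median (0.18) and mean (-0.11) differed in sign.

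**Figure D4:**
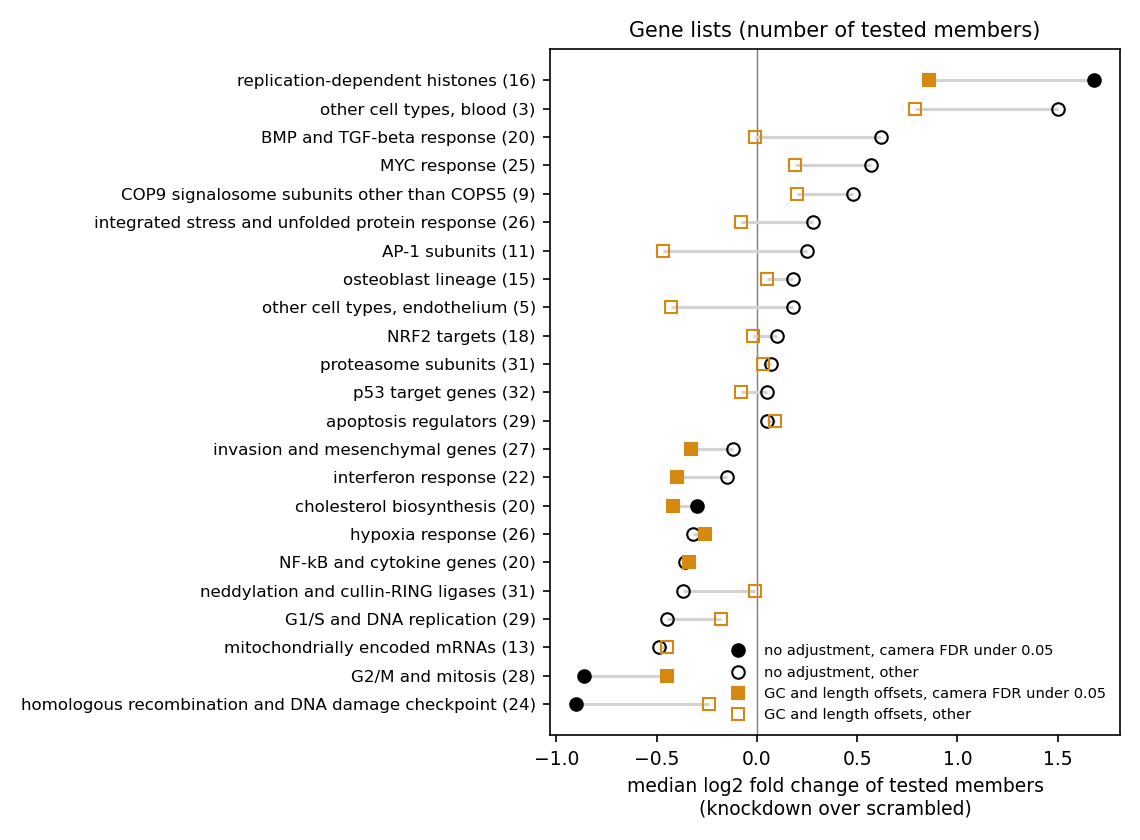
Median log2 fold change, knockdown over scrambled, of the tested members of 23 gene lists (number of members in brackets), without correction (circles) and with GC and length offsets (squares), filled where camera's adjusted p at a preset correlation was under 0.05. The G2/M (-0.86 and -0.45), cholesterol (-0.30 and -0.42) and histone (1.68 and 0.86) lists are filled in both.

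In all, 4 of 23 lists passed camera without correction, 3 of them downward. With an estimated correlation 0 of 23 passed, 1 list had an unadjusted p under 0.05, and 11 passed with fry, which does not compare a list with other genes and passed a list of unchanged genes in the simulation. In the corrected fit 7 passed, 3 of them in the same direction as without correction, and with an estimated correlation 0 passed, with 2 at an unadjusted p under 0.05.

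The authors' deposited table had tested 17999 genes and called 4167 at a q of at most 0.05, of which 2615 were higher and 1552 lower in the knockdown. Of 3995 genes called in the authors' deposited table and tested here, 3800 were called in the same direction and 3 in the opposite one. The authors' deposited table gave COPS5 a log2 fold change of -1.40 (q = 0.0169), MDM2 -0.84 (q = 0.144) and CDKN1A 0.09 (q = 0.809). A further 4827 genes were called here and not in the authors' deposited table.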

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

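These loci were looked at after the results had been seen, and no test was made on them. The locus of MMP1, MMP3 and MMP10, matrix-degrading enzymes of invading cells, gave a signal that no comparison used, since Cuffdiff skipped it in the scrambled libraries, with a status given to loci of too many fragments, and measured it in the knockdown libraries (chromosome 11, 102746968 to 102843803). MMP1, interstitial collagenase, had 78991, 70166 and 189743 fragments in knockdown libraries 0, 1 and 2, a mean of 112967 ± 66636 (SD, n = 3). MMP3 had 260, 271 and 2405 fragments, a mean of 979 ± 1235, and MMP10 had 103, 62 and 76, a mean of 80 ± 21. No scrambled value was measured, so no fold change can be given. The largest locus that Cuffdiff did measure held 219375 to 248928 fragments in the scrambled libraries.

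In the same way 9 loci with 40 genes were skipped in the knockdown libraries alone, of which 8 held a gene of the 7SL RNA of the signal recognition particle. Another 6 loci with 20 genes were skipped in both groups.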

How the results depend on the processing

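The corrected fits, protein-coding genes only, genes with a failed estimate left out and the pair of libraries left out were chosen after the data had been seen. COPS5 fell in every alternative run (log2 -1.62 to -1.22, adjusted p from 1.1e-10 to 0.0053), and the p53 target list passed in none (median -0.09 to 0.15, adjusted p from 0.078 to 0.942). Leaving out 1 library at a time gave 3338 to 4086 genes higher, 3486 to 4452 lower, 4 to 5 lists, COPS5 from -1.54 to -1.32 and the p53 list's median from -0.07 to 0.06. The count of genes higher became 2826 with a 2-fold minimum, 2571 at an FDR of 0.01, 2615 in the authors' deposited table, 2626 with GC and length offsets and 2412 with GC offsets. The count lower became 2634 and 2666 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), 2215 with a 2-fold minimum, 2758 at 0.01, 1552 in the authors' deposited table, 2662 with GC and length offsets and 2660 with GC offsets. The number of lists became 9 with no filter beyond 1 count, 0 with an estimated correlation, where camera had 1 at an unadjusted p under 0.05, 11 with fry, 7 with GC and length offsets, 8 with GC offsets, and 8 with both offsets and without knockdown library 0 and scrambled library 0. Without those 2 libraries and no offsets, 4626 genes were higher and 5067 lower, and with offsets 3505 and 3463. Stricter thresholds lower counts by construction, and the cause was not tested for the other settings. Library size alone moved the median of all genes by -0.11. With GC and length offsets the medians of the p53 (-0.08), integrated stress (-0.08), AP-1 (-0.47), NRF2 (-0.02), BMP (-0.01) and endothelial (-0.43) lists changed sign from above 0 to below 0.

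Values of named genes under the settings fixed in advance kept direction and side of the threshold in 1527 of 1581 cases, 53 lost the threshold, 1 gained it and 0 turned. Under the added ones, 560 of 636 kept both, 51 lost it, 4 gained it and 21 turned. With GC and length offsets these were CDKN1A (-0.78), COPS9 (-0.46), UBE2M (-0.64), ATF2 (0.006), BATF3 (-0.81) and ENO1 (-0.21). With GC offsets they were CDKN1A (-0.75), COPS9 (-0.21), UBE2M (-0.55), BATF3 (-0.63), ENO1 (-0.18), BMP7 (-0.009), MT-ND3 (0.21), MT-ND4L (0.076) and TIE1 (-0.091). With offsets and without both libraries they were CDKN1A (-0.77), COPS6 (-0.03), COPS9 (-0.044), UBE2M (-0.17), ATF2 (0.005) and BATF3 (-0.33). The offsets remove the relation to GC content by construction. No paired analysis was possible because the deposited table's library numbers match no sample title. Leaving out gene entries that carry several gene symbols was not run, since 0 entries did.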

Other observations

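The gene families in the next paragraph and TAGLN were chosen after their values had been seen, and so was the test of S phase; the other tests here were written down before their outcome, though after the pattern they bear on.

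In these families, which were not tested as sets, nuclear genes of ribosomes and of respiratory complex I more often rose than fell. Of 80 cytosolic ribosomal protein genes tested, 41 rose and 1 fell (median log2 fold change 0.46), and 31 rose and 6 fell in the corrected fit (median 0.31), with 23 rising in both. Of 75 mitochondrial ribosomal protein genes, 33 rose and 7 fell (corrected 21 and 8, with 14 rising and 3 falling in both). Of 37 nuclear genes of respiratory complex I 16 rose and 4 fell (corrected 15 and 4, with 10 rising and 0 falling in both). Of 12 RNA polymerase II subunits 9 rose and 1 fell (corrected 5 and 1, with 3 rising and 1 falling in both). Ribosomal protein genes have many processed pseudogenes, so their values are uncertain. Of 35 kinesins, motor proteins of mitosis and transport, 18 fell and 4 rose (corrected 13 and 2, with 11 falling in both). Of 25 integrins 8 fell and 5 rose (corrected 10 and 5). Of 26 collagens 7 rose and 3 fell, against 4 and 7 in the corrected fit, where the median went from 0.71 to -0.17. TAGLN, a gene of the actin cytoskeleton of smooth muscle, rose from 2.43 ± 0.52 to 26.9 ± 1.77 CPM (SD, n = 3), a log2 fold change of 3.47 (SE 0.22, corrected 2.72).

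The first pattern is the rise of fold change with GC content. Lower depth of the knockdown libraries is argued against, since rho was 0.78 after all libraries were thinned to 19.3 M fragments and 0.779 before. Uneven recovery of fragments by GC content may contribute, since libraries of 1 group also differed along GC content: rho between GC content and a library's deviation from the other 2 of its group reached 0.635 in knockdown library 0 and -0.533 in scrambled library 0. Knockdown library 0 also had the lowest COPS5 level of all libraries (19.2 CPM), and scrambled library 0 the highest (73.8 CPM). The differences within groups thus cannot tell uneven recovery from an effect of the knockdown. The trend as fitted by the splines is argued against as the whole source of the changed genes, since 33.2% of tested genes passed with the correction. Uneven recovery that the splines do not capture could still give such calls, so it is not excluded as their source. Of the 5288 genes that passed with the correction, 3361 had been called in the same direction without it. An effect of the knockdown on GC-rich genes (rho 0.779) stays open and cannot be told apart from a difference in library preparation between the groups, since both follow the groups. A rho of this size is not particular to the real groups. When the libraries were split into 3 and 3 across the groups, its size ranged from 0.17 to 0.816. The values 0.816, 0.802 and 0.793 exceeded that of the real split.

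The second pattern is the rise of histone and short non-coding RNA genes. The GC and length trend may explain a part or all of it and stays open: the histone median went from 1.68 to 0.86 with the correction, with a 95% bootstrap interval over genes of 0.27 to 1.45, and the adjusted p of the list was 0.675 with an estimated correlation. Better recovery of short RNAs stays open, since 132 coding genes under 700 nt were higher than coding genes of matched GC content by a median log2 of 0.19 (95% bootstrap interval over genes 0.06 to 0.34), less than the histone rise. The G1/S list had a median of -0.45, below 0 and below the 0.029 of all tested genes, which was the outcome written down against more cells in S phase. That explanation still stays open, since the 95% bootstrap interval of that median over genes ran from -0.69 to 0.47. In the corrected fit the median was -0.18, and 2 genes rose and 9 fell. All 3 intervals resample genes of the same libraries as if independent. They do not measure the spread between samples and may be too narrow.

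Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 8630 genes with edgeR and the highest of the other 9 gave 0, with 24 to 829 genes at an unadjusted p under 0.05. In the corrected fit the real split gave 5288 genes and the highest other 0, with 89 to 1587 at an unadjusted p under 0.05. As many genes as the real split were thus found in 1 of 10 splits in both fits, and 10 splits are too few for a share under 0.05, so a division of the libraries by other causes is neither excluded nor shown. For the gene lists the real split gave 4 and the highest other 6, and 5 of 10 splits gave as many lists as the real one.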
